A study of Mus musculus with 15 samples.

How the data were processed

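RNA was taken from the livers of 15 male mice in 4 groups: ethanol-fed Aldh2-/- (n = 4), ethanol-fed WT (n = 5), pair-fed Aldh2-/- (n = 3) and pair-fed WT (n = 3). The labels give an age of 8 to 10 weeks. It is not taken as the age at death, since dosing with carbon tetrachloride lasted 8 weeks. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with a VAHTS Universal V10 kit and sequenced as paired reads of 150 bp on a NovaSeq instrument. Per the submitters' processing notes, reads were trimmed with fastp, aligned to mm10 with HISAT2 and counted with HTSeq; no versions or annotation were given.

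The deposited values were taken as FPKM (fragments per kilobase of gene, each library scaled to its own total), computed by the authors, in 2 tables, 1 per diet, with the same 23509 gene symbols. A further scaling factor per library could not be checked without total counts, and the depths below assume that there was none. Raw reads were not used here. Low values lay at whole multiples of a smallest step in 26187 of 26201 cases (99.9%, tolerance 0.01 of a step, 3026 genes), which gave the relative depth of the libraries: 90.0% to 111.0% of their mean, a ratio of 1.23 between the deepest and the shallowest. Of 134 single-exon genes, 17 shared the commonest depth of 1 library, 38.6 M fragments in bins of 0.1 M. Carried over by the relative depth, it put the libraries at 31.5 to 38.9 M fragments. It is an inferred figure, and the total counts were not given. Gene positions are those of GENCODE vM21 on GRCm38 (mm10). Of 128 genes taken by the rule for named genes and looked up, 125 had 1 gene model there and 3, mitochondrial genes, were not matched by symbol.

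Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) on log2(FPKM + 1), over genes with a mean of at least 0.5 FPKM in the fit. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, were called. The genotype comparisons used the 2 groups of 1 table. The interaction (the genotype effect under ethanol minus that under pair-feeding) and the diet comparisons used a joint fit of all 4 groups, and an offset between the tables cancels in the interaction only. Aldh2 was also tested with an exact two-sided permutation test within each diet, run in R. Gene lists, 43 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01, and 42 of them had at least 5 tested members. Of 1036 list entries, 13 were not in the tables and 14 were found under another name. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.

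The rule for named genes was also fixed before the data were examined. It took Aldh2, the 7 largest rises and 7 largest falls with a mean of at least 2 FPKM in the higher group and no overlap between the libraries of both groups, up to 4 members with the smallest p from each list called or holding called genes, and a panel of 15 genes. For the interaction it took the 5 largest in each direction. Not every gene that the rule took is named.

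Alternatives were a pseudocount of 0.1, no filter or a mean of at least 2 FPKM, rescaling to a common sum, median-ratio rescaling, quantile normalization, robust variances, library quality weights, a 2-fold minimum, a fit of the other set of groups, a block by the replicate number, and leaving out each library in turn. For lists, an estimated correlation and the rotation test fry were added. Removal of the mitochondrial genes and of the ethanol libraries WT 5 and Aldh2-/- 90 was chosen after seeing the data. The procedure was tested on simulated data, in which 100 genes per comparison were changed by 1 on the log2 scale, 100 by 0.5 and a list of 25 more was raised. It recovered 83% of the first 100 under ethanol, 61% under pair-feeding and 50% in the interaction, and 39%, 5% and 10% of the second. Of all genes called, those of the raised list included, 4 of 135, 5 of 73 and 1 of 62 were unchanged ones. Simulated genes were drawn independently of each other, with no shift shared by a library and few genes changed. These rates therefore need not hold for the real data.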

Results

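Aldehyde dehydrogenase 2, the product of Aldh2, is the mitochondrial enzyme that turns acetaldehyde from ethanol into acetate. Bulk RNA-seq of liver was available for 15 male mice in 4 groups, formed by genotype (Aldh2-/- or C57BL/6 wild type, WT) and diet (ethanol or pair-fed control). Carbon tetrachloride (CCl4) is a liver toxin that causes fibrosis on repeated dosing. By the sample annotation, all 4 groups were also given it by intraperitoneal injection 2 times per week for 8 weeks. They were killed 24 h after the last dose. The sample titles, however, name CCl4 for the ethanol groups only. The ethanol groups held 4 Aldh2-/- and 5 WT libraries, and the pair-fed groups 3 of each genotype. By the annotation, no mice without CCl4 were analysed here, and each comparison is between livers exposed to the toxin. If the pair-fed livers were not exposed, the diet and interaction comparisons would also hold the effect of CCl4. Values were FPKM for 23509 genes. Summed FPKM ran from 509194 to 624277 per library, and the smallest steps in low genes put the depth of the libraries between 90.0% and 111.0% of their mean. Mitochondrially encoded transcripts took 15.2% to 24.2% of the summed FPKM in pair-fed WT libraries and 6.90% to 10.8% in pair-fed Aldh2-/- libraries. In ethanol-fed livers the share was 6.68% to 9.72%, except in WT 5 (13.6%) and Aldh2-/- 90 (18.2%). RNA quality values were not analysed here. The adjusted p-values below for single genes set a difference against the spread between these libraries. Those of camera set the genes of a list against all other genes. At the preset correlation of 0.01 they treat the members of a list as nearly independent.

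The targeted gene separated the genotypes in every library. Aldh2 (chromosome 5, 121566027-121593824, minus strand, GRCm38, a protein-coding gene) stood at 10.3 ± 1.12 against 634 ± 60.8 FPKM in ethanol-fed Aldh2-/- and WT livers (means ± SD, n = 4 and 5). Pair-fed livers held 6.75 ± 0.171 against 290.0 ± 16.9 FPKM (n = 3 and 3). The highest value in an Aldh2-/- library was 11.5 FPKM and the lowest in a WT library 277 FPKM. The difference of mean log2(FPKM + 1) was -5.81 under ethanol (exact two-sided permutation p = 0.00794, the smallest that 126 splits allow) and -5.23 under pair-feeding (exact two-sided permutation p = 0.10, the smallest that 3 against 3 allows). In WT livers Aldh2 was 2.19-fold higher in the ethanol than in the pair-fed group (log2 change 1.12, adjusted p = 4.84e-05 by limma). Diet coincided with the deposited table in that last comparison.

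**Figure D1:**
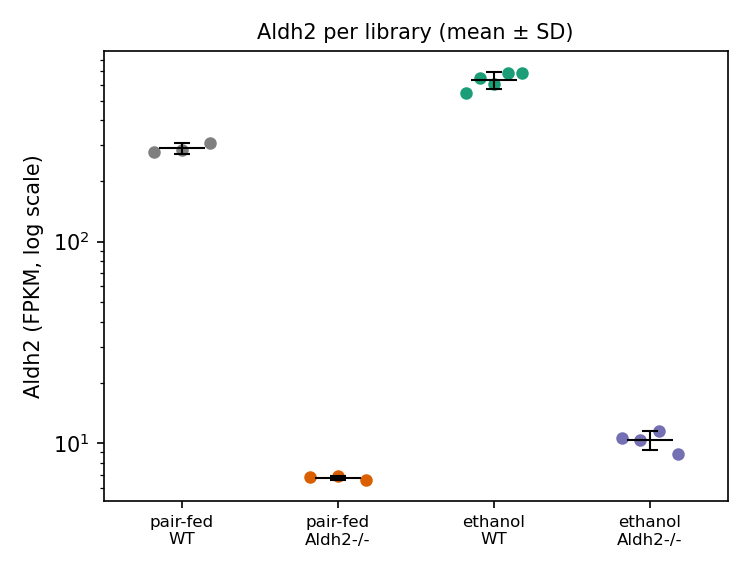
Aldh2 level of each of the 15 libraries in FPKM on a log axis, by group, with the group mean as a line and the SD as error bars. The Aldh2-/- libraries lay between 6.57 and 11.5 FPKM and the WT libraries between 277 and 688 FPKM.

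The first comparison asked what loss of Aldh2 changed in the fibrotic liver under ethanol. On the log2(FPKM + 1) scale, the largest rises in Aldh2-/- livers were in Ddit4, a stress-induced inhibitor of mTOR signalling (288 ± 64.8 against 24.5 ± 20.2 FPKM, means ± SD, n = 4 and 5), and Igfbp1, a secreted binding protein of insulin-like growth factors (1572 ± 726 against 141 ± 84.2 FPKM). Spink1, a trypsin inhibitor, was 34.4-fold higher, the oestrogen sulfotransferase gene Sult1e1 31.7-fold (76.5-fold without WT 5), the trefoil peptide gene Tff3 15.7-fold and Cdc42ep5, an effector of the GTPase Cdc42, 11.3-fold. Among the largest falls were those of G0s2, an inhibitor of the lipase that clears lipid droplets (20.7 ± 12.1 against 218 ± 48.99 FPKM), Inhbe, a secreted hepatokine (0.564 ± 0.695 against 12.4 ± 4.88 FPKM; 22.1-fold lower, and 55.8-fold without Aldh2-/- 89), and the metabolic hormone gene Fgf21 (0.289 ± 0.2203 against 6.15 ± 2.09 FPKM). Bdh1, a mitochondrial enzyme of ketone body metabolism, fell from 77.3 ± 21.1 to 14.8 ± 4.77 FPKM, and Cyp2b9 from 55.1 ± 15.5 to 9.18 ± 6.41 FPKM. For Cyp2b9 the log2 change was -2.67 ± 0.41 (SE, adjusted p = 0.000921). Serpina1e rose 9.52-fold (15.6-fold without WT 7), but it belongs to a cluster of near-identical copies between which reads may be split.

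Markers of several cell types other than hepatocytes were higher in ethanol-fed Aldh2-/- livers. Of 19 monocyte-derived macrophage markers tested, 17 rose and none fell, among them Gpnmb, a gene of lipid-laden and scar-associated macrophages (63.9 ± 21.96 against 7.74 ± 2.41 FPKM), Cd14, a co-receptor for bacterial lipopolysaccharide (4.12-fold), and Adgre1 (2.08-fold). Liver endothelial markers rose in 19 of 22 members, including the sinusoidal receptors Lyve1 (3.37-fold) and Stab2 (2.49-fold). Kupffer cell markers rose in 11 of 15 members and fell in 1, with the complement gene C1qb at 169 ± 49.2 against 43.1 ± 6.101 FPKM. Neutrophil markers rose in 7 of 8, such as S100a9 (3.83-fold). All 11 blood cell markers rose, including the haemoglobin gene Hbb-bt (7.44-fold), whose near-identical copies share reads, and the platelet chemokine gene Pf4 (10.9-fold, and 7.15-fold without Aldh2-/- 89). Camera, the limma set test, called each of these 5 lists with a preset correlation (adjusted p from 3.03e-08 to 0.000778). With an estimated correlation none was called, at adjusted p = 0.412 for macrophage, 0.416 for endothelial and 0.412 for blood cell markers, 0.412 for Kupffer cell and 0.412 for neutrophil markers. Adjusted over the list alone, 17 macrophage, 19 endothelial, 11 Kupffer cell, 7 neutrophil and 11 blood cell markers rose. Dendritic cell and antigen presentation genes rose in 6 of 14 members (7 adjusted over the list alone), and the list was called (adjusted p = 0.00884; 0.501 with an estimated correlation). B and plasma cell markers rose in 1 of 5 and fell in 1, and that list was not called (adjusted p = 0.978). Cholangiocyte markers rose in 6 of 17 members and fell in 2, and the hepatocyte identity list rose in 2 and fell in 3 of 26; neither list was called (adjusted p = 0.262 and 0.428).

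Matrix genes rose with them. In the list of fibrillar collagens and matrix, 21 of 25 members rose and none fell (22 adjusted over the list alone). Examples were Col1a1, the main chain of scar collagen (chromosome 11, 94936224-94953042; 15.2 ± 3.27 against 6.81 ± 2.91 FPKM, log2 change 1.12 ± 0.26, SE, adjusted p = 0.00737), the basement membrane gene Col4a1 (2.15-fold) and Thbs2 (4.28-fold). Matrix remodelling enzymes rose in 15 of 21 members, with Mmp2 at 19.5 ± 3.87 against 3.65 ± 1.56 FPKM and the macrophage elastase gene Mmp12 9.71-fold higher, while Mmp19 fell by 1.13 on the log2 scale. Quiescent stellate cell markers rose in 8 of 12 members, including Lrat, which stores retinol as esters (2.78-fold), and the transcription factor gene Hand2 (3.15-fold). Activated stellate cell markers rose in 9 of 16 and TGF-beta pathway genes in 8 of 17, with Tgfb1 at 9.71 ± 2.898 against 3.92 ± 0.691 FPKM. Acta2, the smooth muscle actin of activated stellate cells, was at 1.74 ± 0.508 against 1.56 ± 0.428 FPKM (adjusted p = 0.662), and Col3a1 at 17.4 ± 5.09 against 13.3 ± 4.18 FPKM (adjusted p = 0.248). Timp1 was at 4.35 ± 2.44 against 1.57 ± 0.776 FPKM (adjusted p = 0.0267), a call lost without Aldh2-/- 86 or 90 or without WT 6, 7 or 12. Camera called these 5 lists at adjusted p from 4.11e-07 to 0.00661. With an estimated correlation the adjusted p was 0.427 for matrix, 0.412 for remodelling, 0.458 for quiescent and 0.576 for activated stellate cell markers, and 0.427 for TGF-beta genes. Fry, which tests a list on its own, did not call the activated stellate list (adjusted p = 0.0619). With adjustment over the list alone, 18 remodelling genes rose and 1 fell, and 9 quiescent, 10 activated stellate and 8 TGF-beta genes rose.

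Cell cycle and p53 target genes also rose. Of 23 proliferation genes 18 rose, including Ccnb1, the cyclin of mitotic entry (3.65 ± 1.47 against 0.4603 ± 0.142 FPKM), and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit (8.196-fold, and 5.36-fold without Aldh2-/- 90). Of 23 genes of the p53 and DNA damage list 17 rose, including Sesn1 (16.1 ± 2.697 against 3.81 ± 0.648 FPKM) and Phlda3 (20.2 ± 4.36 against 5.24 ± 0.926 FPKM). The fetal and tumour-associated list, which holds Spink1 and Tff3, rose in 7 of 15. Inflammatory cytokine and chemokine genes rose in 12 of 21, with Cxcl14 7.91-fold and the adhesion molecule gene Vcam1 2.88-fold higher, whereas Ccl2 was at 0.9105 ± 0.3598 against 0.688 ± 0.3005 FPKM (adjusted p = 0.402). Tnf averaged below 0.13 FPKM in each group and Il6 was listed at 0 in every library but 1 pair-fed Aldh2-/- library, so neither passed the filter of 0.5 FPKM. None of the members of these 4 lists fell. Camera called all 4 (adjusted p from 4.11e-07 to 0.000982), but not with an estimated correlation (adjusted p = 0.412 for proliferation, 0.379 for p53, 0.412 for fetal and 0.427 for cytokine genes). In tests adjusted over the list alone, 18, 18, 11 and 12 members rose in that order.

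Several lists of hepatocyte metabolism were lower and others were not. Cholesterol synthesis genes fell in 18 of 24 members and rose in none, with Hmgcs1, which makes the precursor of mevalonate, at 6.96 ± 1.74 against 32.3 ± 13.96 FPKM and the desaturase gene Sc5d at 11.4 ± 1.57 against 31.3 ± 5.93 FPKM. Fatty acid oxidation and PPAR-alpha targets fell in 26 of 34 and rose in 1, including the acyl-CoA dehydrogenase gene Acadm (130.4 ± 24.5 against 344 ± 67.99 FPKM). In the alcohol and aldehyde list, which contains Aldh2 itself, 15 of 25 fell and 2 rose, with Adh4 at 7.42 ± 1.12 against 19.4 ± 3.36 FPKM and Aldh6a1 at 54.6 ± 12.8 against 104 ± 8.17 FPKM, while the aldo-keto reductase gene Akr1b8 rose 4.82-fold. Adh1 (adjusted p = 0.0643) and Cyp2e1 (adjusted p = 0.0825), both enzymes of ethanol oxidation, were at 901 ± 146 against 1135 ± 83.03 FPKM and 1607 ± 486 against 2265 ± 447 FPKM. Lipid synthesis genes fell in 14 of 25 and rose in 5, with Srebf1, a transcription factor of lipogenesis, falling to 9.31 ± 1.53 from 23.99 ± 4.34 FPKM and Lpin1 rising 3.601-fold. The P450 list fell in 14 of 32 and rose in 4, and bile acid genes fell in 9 of 24 and rose in 2, with Cyp7a1 at 14.9 ± 11.4 against 17.3 ± 2.82 FPKM (adjusted p = 0.365). Cyp7a1 was 1.16-fold lower, and 1.83-fold without Aldh2-/- 96. The albumin gene Alb was at 41100.0 ± 5414 against 53500.0 ± 6190.0 FPKM (adjusted p = 0.0969), Scd1 at 464 ± 153 against 392.3 ± 99.2 FPKM (adjusted p = 0.513) and Plin2, a coat protein of lipid droplets, at 69.9 ± 52.9 against 124 ± 32.2 FPKM (adjusted p = 0.0525). Plin2 was 1.78-fold lower, and 2.82-fold without Aldh2-/- 89. Camera called these 6 lists lower (adjusted p from 3.03e-08 to 0.00931). It did not call gluconeogenesis (5 of 21 higher and 4 lower, adjusted p = 0.841), periportal (4 of 20 higher and 3 lower, 0.397), pericentral (4 of 17 higher and 5 lower, 0.796) or lipid droplet genes (4 of 22 higher and 8 lower, 0.0662). Camera did call the lipid droplet list without Aldh2-/- 89 (adjusted p = 0.00893) or without WT 12 (adjusted p = 0.049). When the correlation was estimated, the adjusted p was 0.422 for cholesterol, 0.412 for oxidation, 0.412 for alcohol, 0.422 for lipid synthesis, 0.412 for P450 and 0.431 for bile acid genes. After quantile normalization the lipid synthesis and bile acid lists were not called either (adjusted p = 0.0567 and 0.0631). Adjusted over the list alone, 22, 26, 19, 14, 15 and 11 members fell in that order.

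In all, 4098 of 11013 genes differed under ethanol, 2365 higher and 1733 lower in Aldh2-/- livers (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05), and the log2 scale with its pseudocount understates the change of low genes. Quantile normalization turned the split to 1903 higher and 2303 lower. Leaving out WT 5 and Aldh2-/- 90, the 2 ethanol libraries with high mitochondrial shares, gave 4315 genes, a choice made after seeing the data.

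Without ethanol, the same genotype comparison gave another picture. Genes of cholesterol synthesis were higher in pair-fed Aldh2-/- livers: all 24 members rose, including the demethylation enzyme genes Nsdhl (42.1 ± 12.4 against 5.03 ± 1.04 FPKM, means ± SD, n = 3 and 3) and Cyp51 (36.5 ± 9.14 against 4.94 ± 1.44 FPKM) and the squalene epoxidase gene Sqle (5.64-fold). Proliferation genes rose in 24 of 27 members, with Ccnb2 at 52.6 ± 13.8 against 12.9 ± 2.72 FPKM and the DNA replication genes Pcna (2.396-fold) and Mcm6 (2.97-fold). Fabp5, a fatty acid binding protein, rose from 10.5 ± 1.32 to 98.3 ± 27.7 FPKM, the neutrophil protease gene Prtn3 22.3-fold (39.01-fold without WT 18), the iron-binding acute phase gene Lcn2 8.02-fold (12.7-fold without WT 18) and Rgs16, a regulator of G protein signalling, 11.2-fold. Sds, the serine dehydratase of periportal hepatocytes, fell from 597 ± 173 to 105 ± 38.5 FPKM.

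All genes together were shifted in this comparison: the median log2 change over the 11138 genes tested was 0.26, and it was 0.01 after median-ratio rescaling. That method sets the median near 0 by construction, so the value of 0.01 says nothing about the cause of the shift. Relative to the median of 0.26, log2 changes were 2.56 for Nsdhl, 2.40 for Cyp51, 1.68 for Ccnb2, 2.81 for Fabp5, 2.80 for Lcn2 and -2.78 for Sds. After median-ratio rescaling, 19 cholesterol genes and 8 proliferation genes were still called, all higher. Inflammatory cytokine genes rose in 11 of 22 members (3 after rescaling), among them Ccl9 (4.2-fold) and Cxcl14 (7.604-fold). Camera called these 3 lists higher (adjusted p = 2.84e-14, 6.18e-07 and 0.0376), but with an estimated correlation the adjusted p was 0.304, 0.492 and 0.492. The cytokine call was also lost without Aldh2-/- 1, WT 18 or WT 20, and fry did not call proliferation genes (adjusted p = 0.0515). In tests adjusted over the list alone, 24, 27 and 11 members rose.

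Lipid synthesis genes rose in 12 of 25 and fell in 1, with Fasn, the fatty acid synthase gene, at 13.2 ± 2.08 against 4.86 ± 1.01 FPKM and the desaturase gene Fads1 3.47-fold higher. The list was not called as deposited (adjusted p = 0.0569; 0.492 with an estimated correlation and 0.0118 by fry), but was after median-ratio rescaling (adjusted p = 0.00905), with 4 members called higher, and without Aldh2-/- 1, Aldh2-/- 9 or WT 20 (adjusted p from 0.0111 to 0.0197). The serine synthesis genes Phgdh and Psat1, of the integrated stress list, rose 4.97-fold and 4.71-fold. In that list 11 of 25 members were higher as deposited and 2 after median-ratio rescaling. It was not called as deposited (adjusted p = 0.21; 0.859 with an estimated correlation and 0.143 by fry), but was after rescaling (adjusted p = 0.0214), after quantile normalization (adjusted p = 0.00352) and without Aldh2-/- 9 (adjusted p = 0.000658). Psat1 was not called without WT 20. In the acute phase list 16 of 28 members were higher and 2 lower, but 1 was higher and 4 lower after median-ratio rescaling. That list was not called (adjusted p = 0.538; 0.859 with an estimated correlation, 0.0805 after rescaling and 0.00619 after quantile normalization, which calls it higher). Saa2 and Saa1, near-identical serum amyloid genes that share reads, were at 2144 ± 1660.0 against 108 ± 99.3 FPKM and 2562 ± 1871 against 166 ± 146 FPKM (adjusted p = 0.0299 and 0.0298), and Orm2 was at 418 ± 312 against 49.7 ± 33.9 FPKM (adjusted p = 0.0211). These genes were 19.8, 15.4 and 8.405-fold higher, but Saa2 37.2-fold and Saa1 27.6-fold without WT 19, and Orm2 5.23-fold without Aldh2-/- 2 and 13.7-fold without WT 18. The Saa1 and Saa2 calls were lost after median-ratio rescaling and without Aldh2-/- 1 or 2 or WT 18 or 20. The Orm2 call was lost after rescaling and without Aldh2-/- 1 or WT 20. Hamp, which encodes the iron hormone hepcidin, fell from 4837 ± 418 to 1805 ± 119 FPKM.

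Mitochondrially encoded genes were lower in pair-fed Aldh2-/- livers in 11 of 13 members, with COX3 at 246 ± 48.7 against 799.8 ± 193 FPKM and ND5 at 1978 ± 488 against 5842 ± 2154 FPKM. Periportal hepatocyte genes fell in 11 of 20 and rose in 1, including Hal, which breaks down histidine (41.4 ± 12.7 against 125 ± 22.02 FPKM), the urea cycle gene Asl (132 ± 24.3 against 430.5 ± 147 FPKM) and Etnppl (10.6 ± 3.704 against 48.4 ± 16.5 FPKM). The P450 list fell in 8 of 30 and rose in 1, with Cyp2a5 at 8.85 ± 4.04 against 37.8 ± 6.75 FPKM. Cyp2e1 was at 299 ± 222 against 1147 ± 365 FPKM (adjusted p = 0.0165; 3.84-fold lower, and 6.68-fold without Aldh2-/- 9), a call lost without Aldh2-/- 1 or WT 20. Cyp4a10, a PPAR-alpha target, fell from 843 ± 203 to 258 ± 87.8 FPKM, in a list where 6 of 34 fell. Camera, which sets a list against all other genes, called these 4 lists lower relative to them (adjusted p from 3.54e-20 to 1.47e-05). Tested against no change with fry, none was called (adjusted p = 0.0615 for mitochondrial, 0.0534 for periportal, 0.152 for P450 and 0.74 for oxidation genes). Of the oxidation genes 28 of 34 were not called, and their log2 changes had a median of 0.04 and a mean of -0.05, of opposite sign. With an estimated correlation the adjusted p was 0.304 for mitochondrial, 0.304 for periportal, 0.304 for P450 and 0.492 for oxidation genes, whose call was also lost without WT 19. With adjustment over the list alone, 12, 13, 8 and 6 members fell in that order. Matrix genes were higher in 8 of 25 members and in none after rescaling, and the list was not called (adjusted p = 0.726). Col1a1 was at 27.2 ± 6.74 against 11.9 ± 4.23 FPKM (adjusted p = 0.0193; 0.0838 after rescaling, and lost without Aldh2-/- 1 or WT 20). Col3a1 was at 37.9 ± 9.52 against 24.99 ± 11.6 FPKM (adjusted p = 0.135) and Acta2 at 13.8 ± 7.44 against 5.02 ± 2.63 FPKM (adjusted p = 0.0776).

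Under pair-feeding 3162 genes were called, 2894 higher and 268 lower in Aldh2-/- livers. This count rested on the scaling and on single libraries: it was 262 higher and 405 lower after median-ratio rescaling, 300 higher and 354 lower after quantile normalization, and 294 genes in all without Aldh2-/- 1, 474 without WT 20 and 1925 without Aldh2-/- 2.

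The interaction asked whether the genotype effect differed between the diets. All 24 cholesterol synthesis genes had a lower genotype effect under ethanol. Their mean log2(FPKM + 1) was 2.91 ± 0.06 in pair-fed WT and 4.38 ± 0.15 in pair-fed Aldh2-/- livers (mean ± SD, n = 3 and 3), but 3.84 ± 0.45 in ethanol-fed WT and 2.77 ± 0.38 in ethanol-fed Aldh2-/- livers (n = 5 and 4). Cyp51 followed this order, at 4.94 ± 1.44, 36.5 ± 9.14, 13.2 ± 6.43 and 4.87 ± 2.05 FPKM (interaction -3.89 ± 0.44 log2, SE, adjusted p = 7.49e-05), and Sqle had an interaction of -3.65. Fgf21 stood at 18.7 ± 9.17 FPKM in pair-fed WT and 66.97 ± 48.9 in pair-fed Aldh2-/- livers, against 6.15 ± 2.09 and 0.289 ± 0.2203 under ethanol (interaction -4.07, adjusted p = 0.000396). Inhbe showed the same sign (interaction -3.79).

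Among genes with a higher genotype effect under ethanol, Got1, the cytosolic aspartate aminotransferase gene, was at 107 ± 15.9 FPKM in pair-fed WT, 33.5 ± 11.1 in pair-fed Aldh2-/-, 301 ± 59.4 in ethanol-fed WT and 1170.0 ± 425 in ethanol-fed Aldh2-/- livers (interaction 3.59 ± 0.37 log2, SE, adjusted p = 4.39e-05). Interactions were 3.88 for Sult1e1, 3.55 for Cdc42ep5, 3.36 for Ddit4 and 3.35 for Etnppl. Saa2 had an interaction of -3.88 (adjusted p = 0.0362), which was lost without any one of 8 libraries and after median-ratio rescaling. Of the fixed panel, Cyp2e1 (1.61), Tgfb1 (0.66), Adh1 (-0.83) and Plin2 (-1.64) were called, with adjusted p from 0.0137 to 0.0491. Adh1 and Plin2 lost the call after rescaling, Cyp2e1 without pair-fed Aldh2-/- 1 or 2 or pair-fed WT 19, and Tgfb1 and Plin2 each without any one of 11 libraries. For Col1a1 the interaction was -0.04 with a 95% interval from -0.93 to 0.85. For Aldh2 itself it was -0.58 (adjusted p = 0.00949; 0.247 after rescaling).

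By list, endothelial markers had a higher genotype effect under ethanol in 14 of 22 members and a lower one in none. Macrophage markers did so in 9 of 20 with 1 lower, blood cell markers in 8 of 11, quiescent stellate cell markers in 7 of 12, matrix genes in 6 of 25 (10 after median-ratio rescaling) and mitochondrial genes in 10 of 13, with none lower in these 4. Lipid synthesis genes had a lower genotype effect in 17 of 25 and a higher one in 1, and proliferation genes a lower one in 11 of 25 (6 after rescaling). Camera called all 9 lists, cholesterol synthesis included (adjusted p from 8.34e-12 to 0.025). When the correlation was estimated, the adjusted p was 0.382 for the cholesterol, endothelial, macrophage, blood cell, quiescent stellate, mitochondrial and lipid synthesis lists, 0.519 for matrix and 0.659 for proliferation genes. The proliferation call was also lost without ethanol-fed Aldh2-/- 86, pair-fed Aldh2-/- 1 or 2 or pair-fed WT 20. Fry did not call macrophage, matrix or proliferation genes (adjusted p = 0.0767, 0.243 and 0.0625). Adjusted over the list alone, 24 cholesterol, 17 lipid synthesis and 11 proliferation genes were lower, and 15 endothelial, 9 macrophage, 9 blood cell, 7 quiescent stellate, 6 matrix and 11 mitochondrial genes higher.

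Of 11157 genes, 4134 had a called interaction, 899 with a higher and 3235 with a lower genotype effect under ethanol. The median over all genes was -0.22 (0.02 after median-ratio rescaling, which centres the libraries by construction), and rescaling turned the split to 1694 higher and 1312 lower. Of the 4134 genes, 2211 were also called in the same direction after rescaling, 899 higher and 1312 lower.

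**Figure D2:**
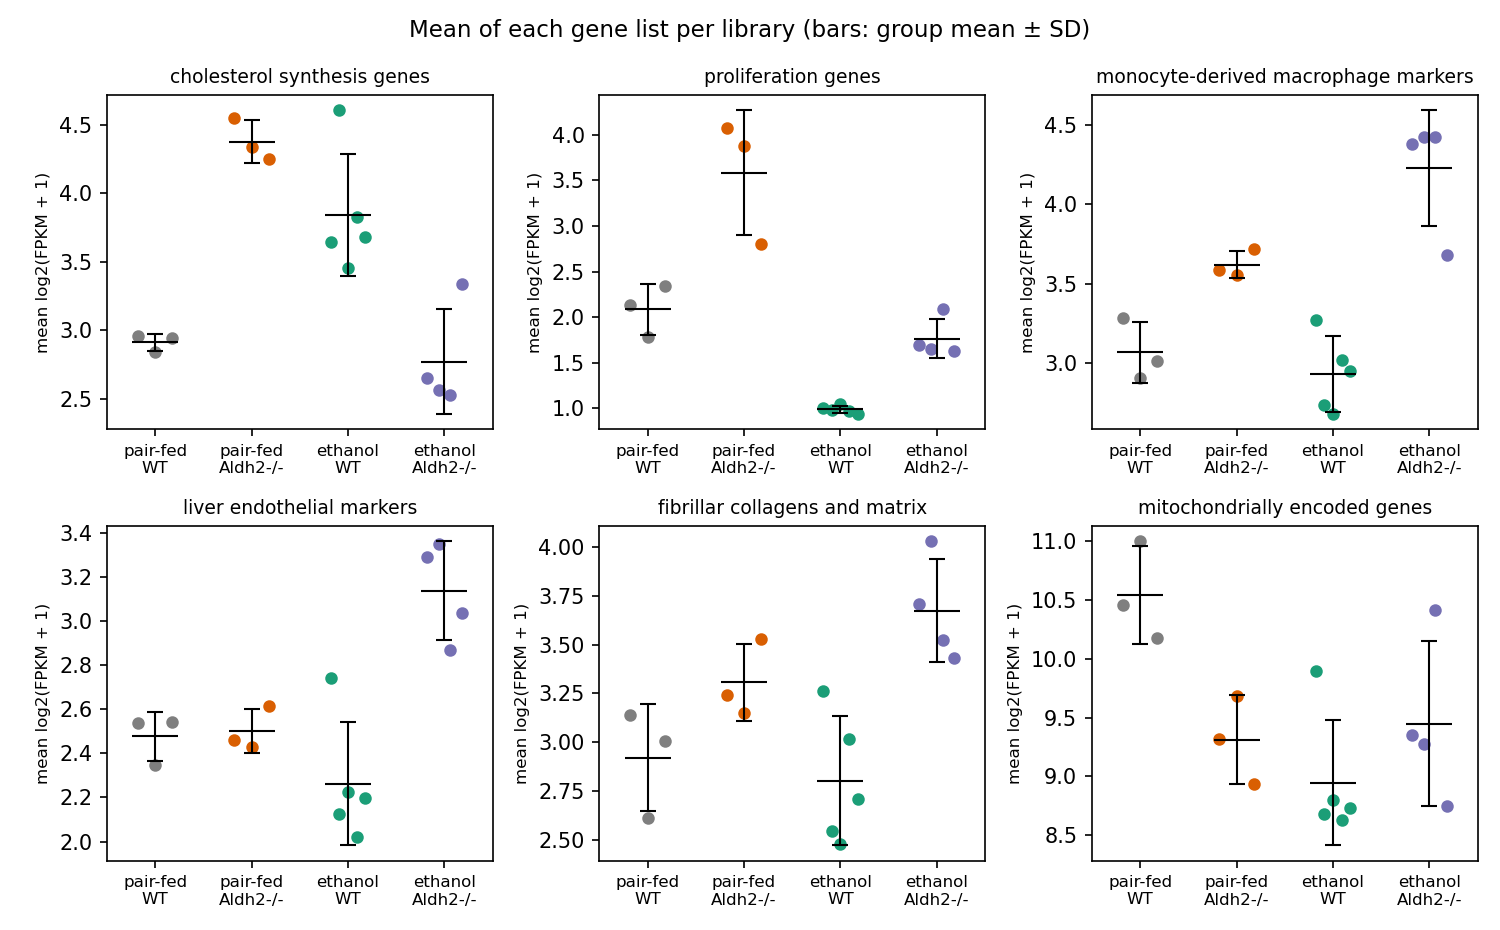
Mean log2(FPKM + 1) over the members of 6 gene lists in each of the 15 libraries, by group, with the group mean as a line and the SD as error bars. Cholesterol synthesis genes averaged 4.38 ± 0.15 in pair-fed and 2.77 ± 0.38 in ethanol-fed Aldh2-/- livers, and proliferation genes 3.58 ± 0.69 and 1.76 ± 0.22.

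Ethanol was then set against pair-feeding within WT livers. Each diet stood in its own deposited table, so diet and table, and any batch that goes with it, cannot be told apart in this comparison and the next. Drug-metabolising genes were higher under ethanol: Cyp2b10, the classical target of the receptor CAR, was at 20.5 ± 10.1 against 0.285 ± 0.1002 FPKM (means ± SD, n = 5 and 3), Cyp2c29 at 252 ± 45.6 against 23.7 ± 2.65 FPKM and Por, the electron donor of P450 enzymes, at 362 ± 25.3 against 129.7 ± 35.3 FPKM. Ugt1a1, Ugt1a9 and Ugt1a6b, glucuronosyltransferase genes that share exons and cannot be counted apart, were 23.3, 57.9 and 24.3-fold higher. Gna12 rose 15.7-fold. Sult2a2, from a family of similar copies, ranged from 1.48 to 183.5 FPKM over the ethanol libraries against a mean of 0.119 ± 0.0379 FPKM.

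Of the P450 list, 17 of 32 members rose and 1 fell, with Cyp3a13 3.01-fold higher. Pericentral hepatocyte genes rose in 9 of 17, including Glul, the glutamine synthetase gene of the cells around the central vein (67.8 ± 9.08 against 27.4 ± 1.63 FPKM). Cyp2e1 was 1.98-fold higher (adjusted p = 0.0347), a call lost after median-ratio rescaling and without ethanol-fed WT 6, 7 or 11 or pair-fed WT 18 or 20. Cholesterol synthesis genes rose in 16 of 24, with Pmvk 3.52-fold higher. No member of these last 2 lists fell. Camera called the 3 lists (adjusted p = 0.00292, 0.00773 and 0.000828), but not with an estimated correlation (adjusted p = 0.573, 0.573 and 0.719). With adjustment over the list alone, 17, 9 and 17 members rose.

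Proliferation genes were lower in ethanol-fed WT livers in 20 of 25 members and higher in 1. Ube2c was at 2.297 ± 0.238 against 32.96 ± 10.7 FPKM, Ccnb2 at 2.21 ± 0.917 against 12.9 ± 2.72 FPKM, Cdc20 at 1.05 ± 0.2099 against 11.6 ± 4.67 FPKM and the survivin gene Birc5 at 0.602 ± 0.135 against 3.67 ± 0.994 FPKM. Interferon response genes fell in 16 of 27, with the transcription factor gene Irf7 at 13.9 ± 2.79 against 53.8 ± 17.4 FPKM and Isg15 at 6.78 ± 1.62 against 24.3 ± 9.18 FPKM. Mitochondrially encoded genes fell in 12 of 13, such as COX1 (13520.0 ± 3817 against 39570.0 ± 11600.0 FPKM) and COX3 (4.33-fold lower). In the list of immediate early and heat shock genes 10 of 19 fell and 1 rose, with Fos at 0.706 ± 0.533 against 11.2 ± 6.36 FPKM. Psmb8, an immunoproteasome gene, fell from 31.5 ± 5.77 to 13.8 ± 1.63 FPKM. Camera called the 4 lists lower (adjusted p from 6.34e-10 to 3.98e-05), and with an estimated correlation the adjusted p was 0.573 for each. In tests adjusted over the list alone, 20, 18, 13 and 10 members fell.

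Angptl8, an insulin-induced inhibitor of lipoprotein lipase, fell from 237 ± 120.4 to 27.1 ± 4.97 FPKM. The male-biased genes Cyp4a12a (1.05 ± 0.306 against 11.1 ± 0.638 FPKM) and Mup21 (2.19 ± 1.84 against 16.9 ± 1.16 FPKM, one of many near-identical copies; 7.72-fold lower, and 11.9-fold without ethanol-fed WT 7) also fell. Elovl3 was at 1.42 ± 0.9751 against 15.2 ± 9.08 FPKM, a call (adjusted p = 0.0201) lost without pair-fed WT 18 or 19. Acta2 was at 1.56 ± 0.428 against 5.02 ± 2.63 FPKM (adjusted p = 0.0138; lost without pair-fed WT 19) and Ccl2 at 0.688 ± 0.3005 against 2.26 ± 1.03 FPKM (adjusted p = 0.00329), while Adgre1 was 2.05-fold higher under ethanol. Col1a1 (adjusted p = 0.0489) and Col3a1 (adjusted p = 0.0369) were lower under ethanol, at 6.81 ± 2.91 against 11.9 ± 4.23 FPKM and 13.3 ± 4.18 against 24.99 ± 11.6 FPKM, and the calls were lost without any one of 9 and 5 libraries. The matrix list, with 1 of 25 members higher and 2 lower, was not called (adjusted p = 0.0688; 0.804 with an estimated correlation), but was called lower without ethanol-fed WT 5, ethanol-fed WT 11 or pair-fed WT 20 (adjusted p from 0.00609 to 0.0319). A total of 4584 genes were called, 3258 higher and 1326 lower under ethanol. The median over all genes was 0.10 on the log2 scale (0.29 with each library rescaled to the same sum), and median-ratio rescaling turned the split to 2098 higher and 2413 lower.

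Within Aldh2-/- livers, ethanol was set against pair-feeding in the same way. Cyp2b10 was at 41.5 ± 28.96 against 0.0838 ± 0.106 FPKM (means ± SD, n = 4 and 3), Got1 at 1170.0 ± 425 against 33.5 ± 11.1 FPKM, the glycerophosphocholine-cleaving enzyme gene Gpcpd1 at 61.7 ± 15.8 against 1.68 ± 0.324 FPKM and Igfbp1 at 1572 ± 726 against 85.2 ± 79.8 FPKM. Cyp2b10 was 495-fold higher, but 1736-fold without pair-fed Aldh2-/- 2 and 330.0-fold without ethanol-fed Aldh2-/- 96, and Igfbp1 18.4-fold, but 39.6-fold without pair-fed Aldh2-/- 1. Ddit4 was 20.3-fold higher under ethanol, the matrix protease gene Mmp7 26.1-fold and Eif4ebp3, a repressor of translation, 20.6-fold. Fgf21 fell from 66.97 ± 48.9 to 0.289 ± 0.2203 FPKM, Angptl8 from 209 ± 16.1 to 9.32 ± 1.98 FPKM and Inhbe from 22.01 ± 5.37 to 0.564 ± 0.695 FPKM. The amyloid genes Saa2 and Saa1, whose reads overlap, were at 22.9 ± 23.96 against 2144 ± 1660.0 FPKM and 67.6 ± 59.8 against 2562 ± 1871 FPKM, and Car3, a carbonic anhydrase gene, at 22.4 ± 18.7 against 212 ± 77.95 FPKM. Of these falls, those of Fgf21 (232-fold, and 141-fold without pair-fed Aldh2-/- 1), Inhbe (39.1-fold, and 98.7-fold without ethanol-fed Aldh2-/- 89), Saa2 (93.5-fold, and 194-fold without ethanol-fed Aldh2-/- 90) and Saa1 (37.9-fold, and 66.2-fold without ethanol-fed Aldh2-/- 90) moved most with 1 library.

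Proliferation genes fell under ethanol in 24 of 25 members, including Mcm6 (1.86 ± 0.195 against 5.55 ± 0.236 FPKM) and Birc5 (1.82 ± 0.833 against 14.4 ± 4.62 FPKM); the cell division gene Cdca3 was 16.6-fold lower. Cholesterol synthesis genes fell in 22 of 24, with Hmgcs1 at 6.96 ± 1.74 against 76.5 ± 21.9 FPKM and Nsdhl at 4.09 ± 1.74 against 42.1 ± 12.4 FPKM. Integrated stress genes fell in 15 of 25 and rose in 1, with Psat1 at 0.606 ± 0.173 against 8.33 ± 4.04 FPKM and the transcription factor gene Atf5 3.62-fold lower. Interferon genes fell in 16 of 27 and rose in 2 (10 and 2 after median-ratio rescaling). Pklr, the liver pyruvate kinase gene of the lipid synthesis list, fell from 53.9 ± 7.62 to 12.7 ± 3.93 FPKM. Camera called the first 4 of these lists lower (adjusted p = 1.69e-09, 3.24e-07, 0.00234 and 0.0101), and the lipid synthesis list, with 15 of 25 lower and 5 higher, was not called (adjusted p = 0.141). With an estimated correlation the adjusted p was 0.674, 0.674, 0.674 and 0.762. Adjusted over the list alone, 25, 22, 15 and 17 members fell.

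The P450 list rose in 18 of 32 and fell in 4, with Cyp2a5 at 75.8 ± 29.4 against 8.85 ± 4.04 FPKM and Por 4.91-fold higher. Pericentral genes rose in 10 of 17 and fell in 1, with Glul at 109.8 ± 5.04 against 30.9 ± 2.96 FPKM and Oat 9.67-fold higher, and Cyp2e1 was at 1607 ± 486 against 299 ± 222 FPKM (5.38-fold, and 9.36-fold without pair-fed Aldh2-/- 9). Periportal genes rose in 10 of 20 and fell in 2, including Asl (1050.0 ± 203 against 132 ± 24.3 FPKM) and Etnppl (16.4-fold). Endothelial markers rose in 14 of 22 and macrophage markers in 10 of 20 with 1 lower, such as Lyve1 (17.3 ± 1.99 against 2.35 ± 0.666 FPKM) and Gpnmb (8.34-fold, and 15.8-fold without pair-fed Aldh2-/- 9). Camera called these 5 lists higher (adjusted p from 1.75e-05 to 0.00107). When the correlation was estimated, the adjusted p was 0.409 for P450 and pericentral genes and 0.674 for periportal, endothelial and macrophage genes. In tests adjusted over the list alone, 19, 11, 11, 14 and 10 members rose. By contrast with the panel genes that follow, the matrix list was called higher, with 9 of 25 members higher and 3 lower (adjusted p = 0.00825; 0.821 with an estimated correlation). So was the list of matrix remodelling enzymes, with 9 of 21 higher and 3 lower (adjusted p = 0.0288; 0.674 with an estimated correlation). Fry called neither (adjusted p = 0.152 and 0.065). Tests adjusted over the list alone gave the same counts for both. The remodelling call was lost after median-ratio rescaling (adjusted p = 0.0654), after quantile normalization (adjusted p = 0.0505) and without ethanol-fed Aldh2-/- 89 (adjusted p = 0.0884). Acta2 was at 1.74 ± 0.508 against 13.8 ± 7.44 FPKM (adjusted p = 0.000111), Col3a1 at 17.4 ± 5.09 against 37.9 ± 9.52 FPKM (adjusted p = 0.00874) and Timp1 at 4.35 ± 2.44 against 13.4 ± 7.69 FPKM (adjusted p = 0.00532), while Adgre1 was 2.64-fold higher.

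In Aldh2-/- livers 5231 genes were called between the diets, 1967 higher and 3264 lower under ethanol. Median-ratio rescaling turned the split to 2638 higher and 2556 lower.

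**Figure D3:**
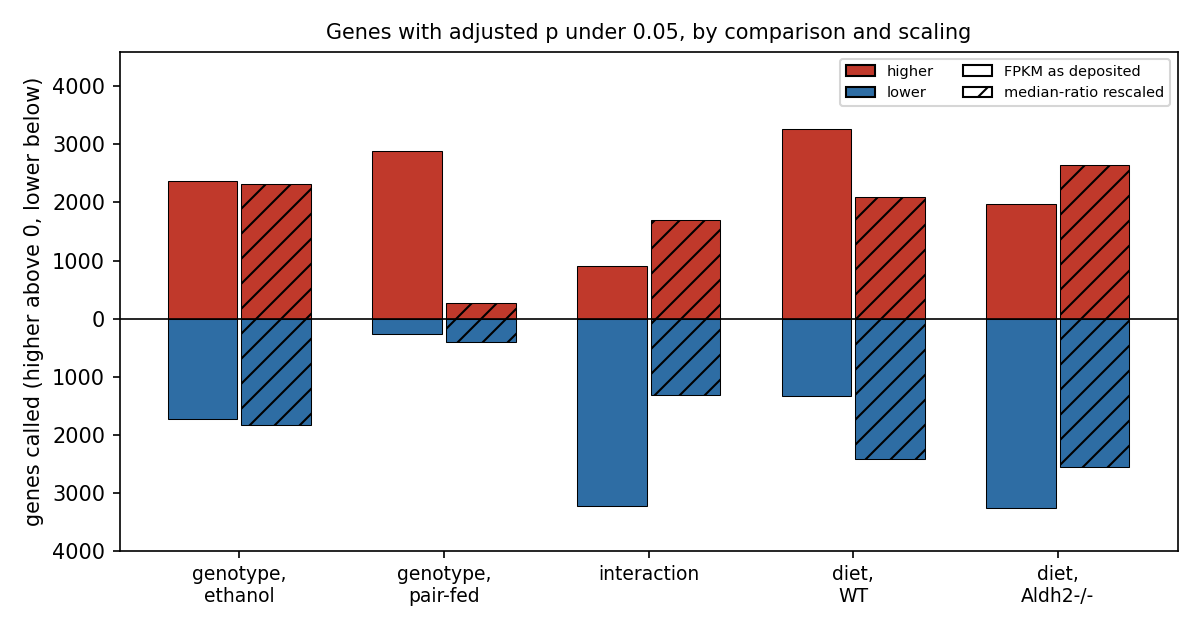
Number of genes with adjusted p under 0.05 in the 5 comparisons, higher above 0 and lower below, for FPKM as deposited (plain bars) and after median-ratio rescaling (hatched bars). The pair-fed genotype comparison went from 2894 higher and 268 lower to 262 and 405, and the ethanol one from 2365 and 1733 to 2323 and 1833.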

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

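The test of a wrong genotype label for WT 5 and the values of the other WT libraries left out in turn were chosen only after the result was seen. With a group of 4 or 5 libraries, chance sets about 1 in 20 groups of normal values apart. In 32 of 236 sets a library stood far from its group, where 11.8 would be expected for independent sets of such values. Most sets were FPKM of genes taken by the rule for naming, which can be skewed and vary together. The excess over 11.8 therefore cannot be read as a count of separate outliers.

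In ethanol-fed WT livers, WT 5 stood far from the other 4 libraries in 11 measures. Its mitochondrial share was 13.6% against 6.68% to 7.62%, and its summed FPKM 569701 against 509194 to 525166. The mitochondrial gene COX1 was at 20190.0 FPKM against 10887 to 13148. Sult1e1 was at 2.12 FPKM against 0.0923 to 0.434, Sult2a2 at 184 FPKM against 1.48 to 41.8 and Mmp7 at 51.8 FPKM against 3.51 to 13.4. The stellate cell genes Lrat and Hand2 were at 3.69 FPKM against 1.52 to 2.01 and 7.28 FPKM against 2.99 to 3.99. The neutrophil gene S100a8 was at 10.9 FPKM against 1.98 to 4.05. Srebf1 (16.3 FPKM against 25.1 to 26.8) and the clock output gene Hlf (6.29 FPKM against 8.21 to 8.37) were low.

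WT 5 lay 41.3% of the way from the other WT libraries to the ethanol-fed Aldh2-/- libraries, over the 4735 genes other than Aldh2 called without it, while the other WT libraries, each left out in the same way together with WT 5, lay at -0.934% to 7.87%. A wrong genotype label is excluded by its Aldh2 level, 47.3 times the highest of the ethanol-fed Aldh2-/- libraries. RNA of an Aldh2-/- liver mixed into the library is argued against by the same gene, which was at 82.7% of the other WT libraries where the mixed fraction predicts 59.3%, a gap of 3.99 SD (2.67 SD with the highest of those values taken off the fraction). A state shared with Aldh2-/- 90 may be the cause, but the deviations of both libraries correlated across 11013 genes at r = 0.318, inside the range of 19 other pairs (-0.517 to 0.404), and genes are not independent replicates. A wrong diet label was not tested. WT 5 correlated with the pair-fed WT libraries at r = 0.967 to 0.970, and the other ethanol-fed WT libraries did so at 0.950 to 0.963. With those other ethanol-fed WT libraries WT 5 correlated at r = 0.977 to 0.983. A difference in the state of this liver stays open and was not tested further.

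Other ethanol-fed WT libraries stood apart in single genes. In WT 7, Serpina1e was at 555 FPKM against 97.4 to 167, Saa1 at 86.2 FPKM against 18.7 to 38.1 and Saa2 at 29.9 FPKM against 6.63 to 12.2. In WT 11, Inhbe was at 20.9 FPKM against 8.96 to 11.7, Bdh1 at 113 FPKM against 57.2 to 72.5 and Cyp2e1 at 3050.0 FPKM against 1952 to 2185. In WT 6, Pmvk was at 6.94 FPKM against 3.45 to 3.96.

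Among ethanol-fed Aldh2-/- livers, library 90 was high in the cell cycle genes Ube2c (38.4 FPKM against 10.6 to 14.8), Ccnb2 (11.3 FPKM against 4.91 to 5.55) and Cdca3 (7.797 FPKM against 3.37 to 3.96), in Saa2 (58.6 FPKM against 6.71 to 13.4) and in COX1 (35445 FPKM against 14772 to 18083). Library 96 was high in the sterol genes Cyp51 (7.91 FPKM against 3.49 to 4.05) and Nsdhl (6.67 FPKM against 3.06 to 3.55), and in Aldh6a1 (73.7 FPKM against 46.03 to 50.04), Ugt1a9 (16.4 FPKM against 0.855 to 2.54) and Cyp2a5 (119 FPKM against 58.2 to 66.8). Library 89 was high in Cxcl14 (10.3 FPKM against 4.56 to 4.81), Igtp (4.76 FPKM against 2.905 to 3.13) and Sult2a2 (15.9 FPKM against 0.959 to 2.79), and library 86 in Cyp2c37 (113 FPKM against 55.2 to 64.1).

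The genotype effect differed between the diets, by the interaction term of limma, in 4134 genes, of which 2211 were also called in the same direction after median-ratio rescaling. Camera called 25 gene lists with a preset correlation but none with an estimated one (smallest adjusted p = 0.382). Differences of the log2 change (ethanol minus pair-feeding) were 3.88 for Sult1e1, 3.59 for Got1, 3.55 for Cdc42ep5, 3.36 for Ddit4, 3.35 for Etnppl, 1.61 for Cyp2e1 and 0.66 for Tgfb1. They were -4.07 for Fgf21, -3.89 for Cyp51, -3.88 for Saa2, -3.79 for Inhbe, -3.65 for Sqle, -1.64 for Plin2, -0.83 for Adh1 and -0.58 for Aldh2. The calls of Saa2, Tgfb1, Plin2 and Cyp2e1 were lost without single libraries, and those of Saa2, Plin2, Adh1 and Aldh2 after median-ratio rescaling.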

How the results depend on the processing

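The removal of mitochondrial genes and of 2 ethanol libraries was chosen after seeing the data. Of the genes taken by the rule for naming, none that was called, with or without an alternative, changed sign. The balance of counts did turn: to 1436 higher and 1450 lower with a filter of 2 FPKM and 1903 and 2303 with quantile normalization for genotype under ethanol, and to 262 and 405 with median-ratio rescaling and 300 and 354 with quantile normalization under pair-feeding. With median-ratio rescaling it turned to 1694 and 1312 in the interaction, 2098 and 2413 for diet in WT and 2638 and 2556 for diet in Aldh2-/- livers. Aldh2 kept its log2 change within -5.86 to -5.74 under ethanol and -5.26 to -5.18 under pair-feeding without any one library. With an estimated correlation, camera called 0 lists in each of the 5 comparisons, with 3 lists at an unadjusted p under 0.05 in the ethanol genotype comparison, 5 in the pair-fed one, 0 in the interaction, 1 for diet in WT and 3 for diet in Aldh2-/- livers. Fry called 24, 6, 9, 16 and 17 lists in that order. Under pair-feeding fry called 6 lists higher and none lower, where camera called 3 higher and 17 lower, and 2 lists were called by both in 1 direction. In the interaction fry called 4 higher and 5 lower, where camera called 22 and 3, and for diet in WT 11 and 5, where camera called 7 and 13. Asking for a 2-fold change as well left 719 genes for genotype under ethanol, 408 under pair-feeding, 1160 in the interaction, 594 for diet in WT and 1256 for diet in Aldh2-/- livers, as a stricter threshold must.

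The pair-fed genotype count of 3162 genes moved most: to 1103 without a filter, 667 with median-ratio rescaling, 654 with quantile normalization, 1862 with mitochondrial genes removed and 4826 with library quality weights. The cause was not tested, except that mitochondrial genes, alone or with the 100 most abundant other genes, were removed to test their share. Without any one library it ran from 294 (without Aldh2-/- 1) to 2870 (without WT 19), and lists from 12 (without WT 19) to 23 (without Aldh2-/- 9). Leaving out 1 of 3 libraries leaves fewer samples. Lists for diet in WT ran from 12 (without pair-fed WT 19) to 22 (without pair-fed WT 20). Without any one library, genes ran from 3175 to 4736 for genotype under ethanol, 3135 to 4644 in the interaction, 3481 to 4998 for diet in WT and 4211 to 5455 for diet in Aldh2-/- livers. Of genes taken by the rule for naming, under the alternatives set out before the data were examined, with all libraries, 704 of 723 values kept their direction and side of the threshold under ethanol, 443 of 494 under pair-feeding, 212 of 239 in the interaction, 410 of 439 for diet in WT and 451 of 472 for diet in Aldh2-/- livers. Many of these genes were taken for large changes or small p in the same data, which favours such shares. Over all genes, 516 of the 3162 pair-fed calls were also made in the same direction after median-ratio rescaling. A replicate block by the number in the descriptions gave 3120 and 2912 genes for genotype under ethanol and pair-feeding, but the numbers did not pair the libraries (correlations of libraries with the same number from -0.0857 to 0.245 under ethanol and -0.0219 to 0.0327 under pair-feeding).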

Other observations

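The tests of a lower hepatocyte share and of blood in the tissue were chosen only after the result was seen. Clock output genes differed between the genotypes under ethanol. Dbp, a clock-controlled transcription factor gene, was at 3.27 ± 1.29 against 24.2 ± 5.93 FPKM in Aldh2-/- and WT livers (means ± SD, n = 4 and 5), Tef at 7.72 ± 0.886 against 17.5 ± 1.64 FPKM and Hlf at 2.25 ± 0.322 against 7.91 ± 0.907 FPKM, while Nfil3, their antagonist, was at 24.7 ± 6.87 against 5.06 ± 0.953 FPKM. Of 18 clock genes 8 fell and 3 rose (10 and 4 adjusted over the list alone). Camera called the list (adjusted p = 0.0261), but not with an estimated correlation (adjusted p = 0.412), after quantile normalization (adjusted p = 0.0599) or without Aldh2-/- 90 (adjusted p = 0.0669). The time of day at which each liver was taken is not analysed here.

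The metallothionein gene Mt1 was at 2582 ± 729.9 against 346 ± 240.0 FPKM and the haem oxygenase gene Hmox1 at 84.2 ± 48.97 against 16.2 ± 3.74 FPKM under ethanol. In the NRF2 and oxidative stress list that holds them, 6 of 31 members rose and 11 fell (8 and 11 adjusted over the list alone). The list was not called (adjusted p = 0.262; 0.819 with an estimated correlation), and its median (-0.11) and mean (0.14) differed in sign. Interferon genes rose in 10 of 24 and fell in 6 (12 and 6 adjusted over the list alone), with Usp18 at 12.5 ± 3.43 against 4.95 ± 1.15 FPKM and the interferon-induced GTPase gene Igtp at 3.48 ± 0.861 against 6.69 ± 1.16 FPKM; the list was not called (adjusted p = 0.397, and 0.857 with an estimated correlation).

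The genotype calls of both diets, from separate libraries, were compared. Of 10627 genes tested in both, 490 were higher in both where lists independent of each other would share 564.3. A further 74 were lower in both against 42.2, 471 were lower under ethanol and higher under pair-feeding against 445.1, and 40 the other way against 53.5. These counts rest on FPKM as deposited, by which 2761 of these genes were called higher under pair-feeding. Median-ratio rescaling left 262 higher and 405 lower in the pair-fed comparison, and the overlap was not counted after it. Across 10626 genes without Aldh2 the log2 changes had r = 0.0383 and rho = -0.0474, and genes are not independent replicates.

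Other splits of the same libraries were counted. For genes, this count argues against chance, without excluding it, for genotype under ethanol and for both diet comparisons. Genotype under ethanol had 4098 genes (highest other split 3973, 1 of 100 drawn from 126). The interaction had 4134 (highest other 1393, 1 of 100 drawn from 2520). Its splits shuffled genotype within each diet, which also breaks a genotype effect common to both diets. That count therefore cannot decide whether chance lies behind a difference between the diets. Diet in WT had 4584 (highest other 50, 1 of 56) and diet in Aldh2-/- livers 5231 (highest other 3331, 1 of 35). Each share was under 0.05, without adjustment over the 5 comparisons. For the diet comparisons the count cannot tell diet from table or batch. The split with 3973 genes is the genotype split with WT 5 on the Aldh2-/- side, and that with 3331 genes places ethanol-fed Aldh2-/- 90 with pair-fed livers, so these come close to the real grouping. Under pair-feeding (3162; highest other 0, 1 of 10; lists 20, highest other 25, 5 of 10) the splits are too few for a share under 0.05. For list counts chance is not excluded: 24 of 100 splits gave at least the 23 lists of genotype under ethanol (highest other 30), 8 of 100 the 25 of the interaction (highest other 28), 15 of 56 the 20 of diet in WT (highest other 24) and 12 of 35 the 19 of diet in Aldh2-/- livers (highest other 28).

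More genes were higher than lower in pair-fed Aldh2-/- livers. A larger mitochondrial share in pair-fed WT libraries (19.0% ± 4.67 against 8.97% ± 1.95, SD, n = 3 and 3) is argued against as the whole cause, since 85.5% of the 1862 genes called with those genes removed were still higher. Mitochondrial and the 100 most abundant other genes together took 63.1% ± 1.93 against 56.0% ± 1.90; with all of them removed 76.1% of 1156 called genes were higher, a value between both predictions, so a contribution of these genes to the shift may remain. An effect of the genotype on many genes stays open as well and was not tested apart from this. RNA quality or handling of the pair-fed WT livers may lie behind their high mitochondrial share, and so behind the lower mitochondrial genes in pair-fed Aldh2-/- and ethanol-fed WT livers, but is not analysed here.

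Markers of several cell types other than hepatocytes were higher in ethanol-fed Aldh2-/- livers. A lower hepatocyte share of the RNA would raise markers that hepatocytes lack alike. The median log2 change of the macrophage list (1.44) exceeded that of the cholangiocyte list (0.348) by 1.09 (95% bootstrap interval 0.391 to 1.66, 10000 resamples of genes). This cannot decide the question, because the cholangiocyte list holds Krt8 and Krt18, which hepatocytes express as well. Both lists also hold Spp1, and genes are not independent replicates. More blood left in the tissue is argued against as the whole cause by the endothelial and matrix lists, whose medians were 0.953 and 1.02, but the blood cell list moved further (all 11 members higher, median 1.57). A lower hepatocyte share, more blood, more macrophages and endothelial cells, or higher levels of these genes per cell may each contribute. Bulk RNA cannot tell these apart.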
